A study of Mus musculus with 4 samples.

How the data were processed

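Gene expression was measured in primary fibroblasts grown from the skin of newborn mice at postnatal day 1. The cells lacked ADAM9, a membrane-anchored metalloprotease that cleaves proteins at the cell surface, or came from wild-type animals. Each genotype had 2 isolations of cells, and each isolation was measured on 1 array, so 4 arrays were compared. Per the labels' protocols, equal numbers of cells were put in square plates of 10 cm, grown for 48 h without treatment and lysed for total RNA with RNAzol. The RNA was then biotin-labelled with a kit that primes from the poly(A) end of transcripts. Nothing in the labels says whether an isolation came from 1 animal or from several, or whether isolations with the same number shared a litter or a day. P-values of the gene tests measure the spread between isolations, and the number of arrays limits the precision.

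The authors deposited 1 value per probe set and array, which per the submitters' processing notes came from Affymetrix Expression Console. The version, the summary algorithm and the log base are not given in the sources used here. The deposited values were taken as log2 because they ran from 1.70 to 14.4 with nearly equal distributions. Array medians were 4.87 and 4.83 in knockout isolations 1 and 2, and 4.87 in each wild-type isolation. If the base was not 2, the fold differences would change and the order of the values would not. No detection calls were used here, so low values have no stated background level, and folds against them depend on it.

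Of 45101 probe sets, 64 were array controls. In the platform annotation, 34958 probe sets named 1 gene and 932 named several genes, with controls included in these counts. Of the non-control probe sets, 9160 named none. Names were updated by Entrez identifier for 34754 probe sets through a RefSeq gene table of assembly GRCm38.p6, which served only for names and for the order of genes along chromosomes. No coordinates are given, because the build behind the platform annotation was not stated. Probe sets with several names or none were left out of the gene tests. Each gene was represented by its probe set with the highest mean over the 4 arrays. Genes whose probe set had a mean above the 40th percentile of all non-control probe sets were tested, which left 13271 of 18193 named genes.

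The genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, no block), and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called changed at an adjusted p under 0.05. The fit had 2 residual degrees of freedom per gene and 2.38 prior degrees of freedom. Standard errors are those of the moderated limma fit. The 34 gene lists were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists. This test sets a list's genes against the other genes, so its p-values rest on the spread across genes and not between isolations. Camera with an estimated correlation and fry were run beside it. Within each list, gene p-values were also adjusted over the list alone. The lists hold pathways, markers of skin fibroblast types and of other skin cells, ribosomal protein genes and immediate-early genes, and 739 of their 928 matched entries were measured. A further list of sex-linked genes was described by array and not tested as a set.

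The genes named were Adam9, then in each direction the 12 genes with the largest log2 difference among those that passed with no overlap between the genotypes. Places left over were filled by genes at an unadjusted p under 0.001, which are said not to have passed. In each list, up to 4 members that passed were named, or the 2 with the largest difference where none passed. The lists, the tests of genes and lists, this rule and all alternatives but 1 were fixed before the data were examined. Some tests of explanations were chosen later, and are said to have been. Genes named outside the rule are said to have been chosen after their values were seen.

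The procedure was tested on 20 simulated data sets of 13271 genes with 200 changed genes each and 2 arrays per genotype. The limma test recovered 3.7% of genes changed by 1 on the log2 scale, 77.9% of those changed by 2, 91.4% by 3 and 96.1% by 4. Of its calls, 5.21% were false. Planting 200 changed genes loosens the adjustment, so these shares may overstate the power in the real data, where 9 genes were called. Camera with the preset correlation found a list of 40 shifted genes in 100% of the data sets, with 1 false list in all of them together. With an estimated correlation it found the list in 0% of the data sets, so at this number of arrays that version had no power for such a list. Genes were drawn independently of each other in these data sets. The rates of lists found and of false lists therefore do not cover lists whose genes vary together.

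The alternatives were the isolation number as a block, other filters on dim probe sets, other normalizations between arrays, a floor on low values, other rules for genes with several probe sets, other eBayes settings, array weights, other thresholds and other set tests. Each array was also left out in turn. Leaving out the genes on the X and Y chromosomes was added after the data had been seen.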

Results

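The arrays covered fibroblasts of newborn mouse skin from ADAM9 knockout animals (n = 2 isolations) and wild-type animals (n = 2), grown in culture without treatment. The comparison addressed which genes differ constitutively when ADAM9 is missing. Over all 13271 genes tested, the values correlated with Pearson's r of 0.979 between the knockout arrays and 0.981 between the wild-type arrays, and with r of 0.956 to 0.975 between arrays of different genotype. These are correlations across genes, which are not independent replicates. The standard deviation of the difference between arrays was 0.440 and 0.415 on the log2 scale within the genotypes and 0.470 to 0.636 between them. The number of genes differing by over 1 log2 unit was 526 between the knockout arrays, 406 between the wild-type arrays and 485 to 1095 between the genotypes, so that the pair with 485, isolation 1 of each genotype, differed at fewer genes than the knockout arrays did. The control probe sets for the 2 ends of the beta-actin transcript, a sign of RNA integrity, differed (poly(A) end minus far end) by 0.147 and 0.198 log2 units in the knockout arrays and by 0.218 and 0.149 in the wild-type arrays.

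Adam9 itself was lower in both knockout arrays. Its 1 probe set (Entrez 11502) had log2 values of 8.33 and 8.55 in the knockout isolations and of 11.58 and 11.70 in the wild-type isolations. The means were 8.44 ± 0.157 (SD, n = 2) and 11.64 ± 0.084 (SD, n = 2), a 9.16-fold lower value in the knockout (log2 difference -3.20, SE 0.147, limma adjusted p = 0.0242). The knockout values remained above the array medians. Whether the probe set lies inside the deleted part of the gene is not given in the sources used here, and outside it the probe set would not check the labels.

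Besides Adam9, 8 genes passed the limma test, 2 higher and 6 lower in the knockout, and 4 of the 9 lie on the sex chromosomes. Xist, the RNA that silences 1 X chromosome in female cells, rose by 6.09 log2 units (SE 0.121, adjusted p = 0.0021). It stood at 10.39 ± 0.015 (SD, n = 2) in the knockout and at 4.30 ± 0.021 in the wild type. The Y-linked genes Eif2s3y, Kdm5d and Uty fell by 6.54, 5.02 and 4.69 log2 units (limma adjusted p = 0.0021, 0.0242 and 0.0242). Each was high in both wild-type arrays and low in both knockout arrays, so the arrays differed in sex-linked expression exactly as they differed in genotype. Ddx3y, also Y-linked, was not among the genes tested. Every gene difference below was measured between these same arrays. Xist had an adjusted p of 0.0772 when probe sets ending in _x_at or _s_at were left out (log2 difference 5.17).

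The other 4 called genes are autosomal. Dlk1, an imprinted gene for a membrane protein that restrains fat cell formation, rose by 2.999 log2 units (SE 0.143, limma adjusted p = 0.0242), from 6.09 ± 0.149 (SD, n = 2) to 9.09 ± 0.062. That value came from 1 of its 2 probe sets. The other, at 4.34 in the knockout and 4.02 in the wild type, differed by 0.32, and the call was lost with it (adjusted p = 0.563). The mean over both gave 1.66 (adjusted p = 0.0771). Ifi202b, an interferon-inducible gene, fell by 5.28 (SE 0.252, adjusted p = 0.0242) and was measured by an _s_at probe set alone. Pla2g7, the secreted enzyme that inactivates platelet-activating factor, fell by 4.09 (SE 0.206, adjusted p = 0.0275), from 11.002 ± 0.318 to 6.91 ± 0.149. Zfp874a, a zinc finger gene, fell by 3.63 (SE 0.145, adjusted p = 0.0242). Dlk1, Ifi202b, Pla2g7 and Zfp874a did not pass with the isolation number as a block (limma adjusted p = 0.104 to 0.143). With any 1 of the 4 arrays left out, 0 genes passed.

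**Figure D1:**
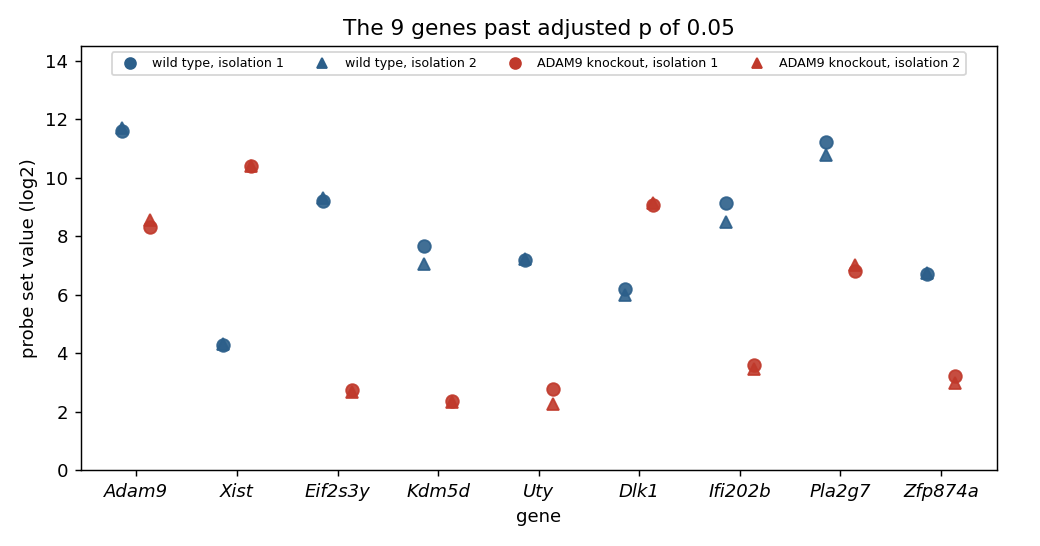
Log2 probe set value of the 9 genes past an adjusted p of 0.05 in each array, with 1 point per array (blue, wild type; red, ADAM9 knockout; circle, isolation 1; triangle, isolation 2). For each gene the 2 arrays of a genotype lie close together and apart from the other genotype, as for Xist at 10.39 against 4.30 and Adam9 at 8.44 against 11.64.

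The count of called genes was small beside the number of genes with low unadjusted p-values. An unadjusted limma p under 0.05 was reached by 1516 genes, where 664 were expected by chance, and 57 genes had an adjusted p under 0.1, of which 39 were higher in the knockout. The genotypes did not overlap for 45.0% of genes, against 33.3% by chance. A difference of at least 2-fold without overlap was seen for 356 genes that were higher and 230 that were lower in the knockout. Among genes that did not pass, Gjb2, which encodes the gap junction protein connexin 26, differed by 4.41 log2 units (SE 0.555, adjusted p = 0.141), Reg1 by 2.90, Col14a1, a fibril-associated collagen, by 2.67 and the protocadherin Pcdh20 by 2.32. The other 6 named on the higher side were the mitosis and proliferation genes Cenpf (2.42, adjusted p = 0.052), Depdc1a (2.53), Nuf2 (2.32), Nusap1 (2.22), Prc1 (2.22) and Mki67 (2.22). Cenpf passed with each of 3 other normalizations and with array weights, and with the mean over its probe sets it differed by 1.43 (limma adjusted p = 0.115; 0.0356 to 0.261 over all settings). Nuf2 passed with array weights (adjusted p = 0.0471; up to 0.311 in other settings). On the lower side, Asb5 differed by -2.52, Rcan2, an inhibitor of calcineurin, by -2.34, Rnf128 by -2.34, Itgb3 by -1.96 and Atp8b4 by -1.90.

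Of the 34 gene lists, 10 passed camera with its preset correlation, 4 on the higher and 6 on the lower side of the knockout. None passed with an estimated correlation (smallest adjusted p = 0.687) or with fry (smallest adjusted p = 0.0610). In lists for which no count adjusted over the list alone is given, 0 genes passed it. Sqle, Sc5d, Cd59a, Masp1, Ngfr, S100b, Col4a5, Col4a2, Pdgfc, Fgf7 and Grem1, named below for passing that adjustment, were chosen after their values were seen. Where leaving out 1 array moved the difference of a gene named below by over 1.5 times, the smallest difference so obtained is given beside it.

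Cell cycle genes stood higher in the knockout as a group. All 42 measured members had positive differences, with a median of 2.02 log2 units, or 4.05-fold (camera adjusted p = 1.98e-31; adjusted p = 0.687 with an estimated correlation). The genotypes did not overlap for 41 of them. No member passed over all genes tested, and 31 passed when adjusted over the list alone, all of them higher. The largest differences were those of Cdc6, which licenses replication origins, at 2.77 (SE 0.998; 1.42 without knockout isolation 2), and the thymidine kinase Tk1 at 2.54 (SE 0.377). Mki67, the proliferation marker, stood at 8.91 ± 0.167 (SD, n = 2) in the knockout and 6.70 ± 0.157 in the wild type. The knockout arrays were not alike in several members. Cdc6 stood at 5.65 in knockout isolation 1 and 8.35 in knockout isolation 2. Ccne2 (5.66 and 8.55), Mcm3 (7.37 and 9.42) and Mcm6 (7.92 and 9.85) were likewise higher in isolation 2. Ccnb2 (10.09 and 8.58) and Cenpa (9.51 and 8.18) were higher in isolation 1. Apart from Cdc6, these members were chosen after their values were seen. The knockout and wild-type arrays compared here also differed in Xist, by 6.09.

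The list of p53 targets and senescence genes stood lower, with a median of -0.26 over 23 genes, 19 of them negative (camera adjusted p = 2.11e-04; adjusted p = 0.710 with an estimated correlation). Cdkn2a, which encodes the cell cycle inhibitors p16 and p19Arf, differed by -1.70 (SE 0.141, limma adjusted p = 0.070) and was the 1 member that passed adjusted over the list alone. Perp, a desmosome-associated p53 target, differed by -3.84 (SE 0.770).

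Genes of the contractile apparatus and of adhesion also stood lower in the knockout. All 24 contractile and myofibroblast genes had negative differences, with a median of -0.38 (camera adjusted p = 2.4e-07; adjusted p = 0.744 with an estimated correlation). Myh11, the smooth muscle myosin heavy chain, differed by -3.12 (SE 0.476) and was the 1 member to pass adjusted over the list alone, and Actg2, a smooth muscle actin, differed by -1.37 (SE 0.423; -0.78 without wild-type isolation 2). With the mean over its probe sets Myh11 differed by -2.03. Without wild-type isolation 2 the list's median was -0.22. Of 29 integrins and adhesion receptors, 24 were negative, with a median of -0.29 (camera adjusted p = 1.73e-04; adjusted p = 0.687 with an estimated correlation). Adjusted over the list alone, 2 members fell, the integrin subunits Itgb3 (-1.96, SE 0.156) and Itga7 (-0.95), the latter named after its value was seen. With the mean over its probe sets Itgb3 differed by -0.997. N-cadherin, Cdh2, differed by -1.19 (SE 0.355).

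The pericyte and smooth muscle markers had a median of -0.55 over 12 genes (camera adjusted p = 0.0324; adjusted p = 0.744 with an estimated correlation), and the call was lost without knockout isolation 2 (median -0.29, adjusted p = 0.166), without a filter on dim probe sets (adjusted p = 0.0731), with a stricter one (adjusted p = 0.0565) and with the isolation number as a block (adjusted p = 0.0816). Myh11, Actg2, Lmod1 and Des are also in the contractile list above, so these lists are not independent of each other. Myh11 was the 1 gene lower adjusted over the list alone. Abcc9, a channel subunit of pericytes, differed by 2.51 (SE 0.779; 1.49 without wild-type isolation 2) and by 0.93 when _x_at and _s_at probe sets were left out. Kcnj8 stood at 8.38 and 5.97 in the knockout arrays and at 5.86 and 4.30 in the wild-type arrays, while Mcam differed by -0.91. Kcnj8 and Mcam were named after their values were seen. The oxidative stress list had a median of -0.42 over 28 genes, with 0 passing adjusted over the list alone (camera adjusted p = 0.0104; adjusted p = 0.744 with an estimated correlation). It was not past the test without wild-type isolation 2 (median -0.04, adjusted p = 0.705) or knockout isolation 2 (median -0.18, adjusted p = 0.197). Without wild-type isolation 1 its median was -0.62. The glutathione transferase Gsta4 differed by -1.15 (SE 0.586; -0.52 without knockout isolation 2) and the metallothionein Mt1 by -1.01 (SE 0.268). Mt1 differed by -0.56 with the mean over its probe sets and by -0.11 when _x_at and _s_at probe sets were left out.

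Cholesterol biosynthesis genes stood higher, with positive differences for all 20 and a median of 0.80 log2 units, or 1.74-fold (camera adjusted p = 5.89e-08; adjusted p = 0.744 with an estimated correlation). Adjusted over the list alone, 3 genes rose, Stard4, Sqle and Sc5d. The sterol transfer gene Stard4 differed by 1.54 (SE 0.153, limma adjusted p = 0.086 over all genes) and the isomerase Idi1 by 1.22 (SE 0.515; 0.67 without wild-type isolation 1). The list's median was 0.40 without knockout isolation 1 and 1.20 without knockout isolation 2. Ribosomal protein genes had a median of 0.12, with all 27 positive and 0 passing adjusted over the list alone (camera adjusted p = 0.0239; adjusted p = 0.744 with an estimated correlation). Rpl8 differed by 0.26 and Rpl14 by 0.24 (0.14 without wild-type isolation 1). That call was lost when values were quantile-normalized again (adjusted p = 0.129), with cyclic loess (adjusted p = 0.0961), and without knockout isolation 2 (adjusted p = 0.324) or wild-type isolation 1 (adjusted p = 0.179).

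**Figure D2:**
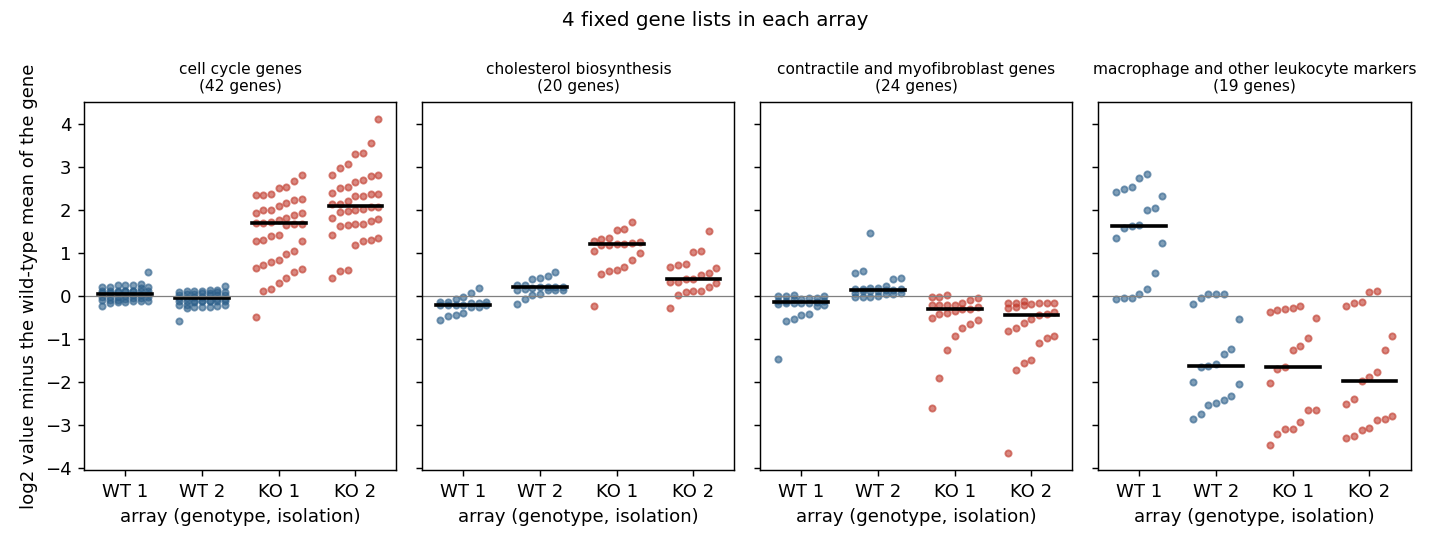
Log2 value of each gene minus its wild-type mean, by array, for cell cycle, cholesterol biosynthesis, contractile and leukocyte genes (1 point per gene; black bar, median of the list in that array). The median of the cell cycle genes was 1.69 and 2.10 in the knockout arrays, and the leukocyte genes were high in wild-type isolation 1.

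Fibroblast markers of the deep dermis and hypodermis stood higher, with a median of 0.39 over 15 genes (camera adjusted p = 0.045; adjusted p = 0.744 with an estimated correlation). Dlk1 rose, by both adjustments, and the other 14 did not pass. Cnn1, Plac8 and Gpx3, named after their values were seen, had negative differences, and all other members had positive ones. The call was lost without knockout isolation 1 (adjusted p = 0.0715) or 2 (median 0.22, adjusted p = 0.222), without wild-type isolation 2 (adjusted p = 0.128), with a stricter filter (adjusted p = 0.209), with median centring (adjusted p = 0.0664), with cyclic loess (adjusted p = 0.0640), with the mean over probe sets (adjusted p = 0.0631) and without _x_at and _s_at probe sets (adjusted p = 0.165). Without wild-type isolation 1 the median was 0.67. General dermal fibroblast markers did not pass (16 genes, median 0.15, camera adjusted p = 0.220). Lumican, Lum, differed by 1.54 (SE 0.772; 0.41 without wild-type isolation 2) and the PDGF receptor Pdgfra by 1.16 (SE 0.549; 0.37 without wild-type isolation 2). Both were lowest in wild-type isolation 2, and without wild-type isolation 1 the list passed (median 0.37, adjusted p = 5.3e-05), while without wild-type isolation 2 its median was -0.030. It also passed with probe sets tested singly (median 0.15, adjusted p = 0.0343). Papillary markers did not pass (11 genes, median 0.19, adjusted p = 0.357), with Col7a1 at -1.59 (-0.91 without wild-type isolation 2) and Dpp4 at 1.05 (0.51 without wild-type isolation 2; 0.32 with the mean over its probe sets).

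Macrophage and other leukocyte markers were high in 1 wild-type array. The median of the 19 genes was 8.44 in wild-type isolation 1, against 4.65 in wild-type isolation 2 and 4.48 and 4.44 in the knockout arrays. The list passed camera on the lower side of the knockout (median -1.70, adjusted p = 1.76e-04; adjusted p = 0.744 with an estimated correlation), with 0 genes passing adjusted over the list alone. Without wild-type isolation 1 the median was -0.29, without wild-type isolation 2 it was -3.34, and without knockout isolation 1 the call was lost (adjusted p = 0.0755). Ctss, a lysosomal protease of macrophages, was 10.07 in wild-type isolation 1 and 3.88 to 4.58 in the other arrays (a difference of -0.53 without wild-type isolation 1), and C1qb, a subunit of complement C1q, was 9.46 and 3.37 to 3.77. Complement genes, whose list shares the C1q genes, did not pass (14 genes, median -0.31, adjusted p = 0.618), and C1qb and C1qa differed by -3.17 (-0.32 without wild-type isolation 1) and -3.03 (-0.50 without wild-type isolation 1). Adjusted over the list alone 1 gene rose, Cd59a (0.78), and 1 fell, Masp1 (-1.12). Without wild-type isolation 2 that list passed (median -0.48, adjusted p = 9.4e-04). Its median was -0.16 without wild-type isolation 1, -0.61 without knockout isolation 1 and -0.058 without knockout isolation 2.

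Markers of the remaining cell types did not pass camera. The medians were 0.00 for keratinocytes (10 genes, adjusted p = 0.582), -0.04 for melanocytes (5 genes, adjusted p = 0.627), 0.17 for endothelial cells (10 genes, adjusted p = 0.582), -0.05 for skeletal muscle (12 genes, adjusted p = 0.357), 0.04 for adipocytes (11 genes, adjusted p = 0.330), 0.06 for Schwann and neural cells (13 genes, adjusted p = 0.367) and -0.01 for cartilage and bone (7 genes, adjusted p = 0.558). Without knockout isolation 1 the endothelial median was 0.0023, without wild-type isolation 1 or 2 it was 0.037 or 0.11, and without knockout isolation 2 it was 0.26. With probe sets tested singly the endothelial list (median 0.19, adjusted p = 0.0334) and the adipocyte list (median 0.13, adjusted p = 0.0275) passed. The keratinocyte mean was -0.56 and its camera direction was down, with Perp at -3.84 and the desmosomal Dsp at -2.49 (-1.53 without wild-type isolation 2). The Schwann and neural mean was -0.13, against a positive median and an upward camera direction. In that list Stmn2, a neuronal microtubule regulator, differed by -4.02 (SE 0.721) and Erbb3 by 0.90 (0.50 with the mean over its probe sets). Adjusted over the list alone 3 genes rose, Erbb3, Ngfr and S100b, and Stmn2 fell. Gpnmb differed by -1.14 (-0.63 without wild-type isolation 1) and Mitf by -0.61 (-0.054 without knockout isolation 2). Of the endothelial genes, Tek differed by 0.66 (0.24 without wild-type isolation 2) and Flt1 by 0.25 (-0.035 without wild-type isolation 1), and of the muscle genes Acta1 by -1.35 (-0.63 without wild-type isolation 2) and Tnnc1 by -0.48 (-0.079 without knockout isolation 2). Of the adipocyte genes, Lpl differed by 1.39 (0.89 without knockout isolation 1) and Cebpa by 1.10 (0.67 without wild-type isolation 2), and of the cartilage genes Sox9 by -0.36 and Col9a3 by -0.24 (-0.16 without wild-type isolation 2).

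The lists of proteases and of the extracellular matrix did not pass camera. ADAM and ADAMTS proteases had a median of 0.01 (22 genes, camera adjusted p = 0.916), with Adam8 at -1.66 (SE 0.816) and Adamts9 at 1.495 (0.82 without knockout isolation 2). Adam8 was 8.03 in wild-type isolation 1, the array with high leukocyte genes, and 5.05 to 5.66 in the others, and it differed by -0.47 without that array. Matrix metalloproteinases, plasminogen activators and their inhibitors had a median of -0.02 (20 genes, adjusted p = 0.627), with Mmp16 at -1.02 and Timp1 at 0.94 (0.39 without knockout isolation 2). For reported ADAM9 substrates the median was -0.18 (17 genes, adjusted p = 0.357), with Igfbp5 at -1.68 (-0.86 without knockout isolation 2) and Il1r2 at 1.03 (0.34 without wild-type isolation 2). Without a filter on dim probe sets the median of the substrates was -0.0089. Igfbp5 differed by -0.97 with the mean over its probe sets and by -0.25 when _x_at and _s_at probe sets were left out. No gene of these 3 lists passed adjusted over the list alone. Collagens and their processing enzymes had a median of -0.07 (35 genes, adjusted p = 0.330), and adjusted over the list alone 1 gene rose, Col14a1, and 2 fell, Col4a5 and Col4a2. Without wild-type isolation 2 the list passed (median -0.15, adjusted p = 0.0261), while without wild-type isolation 1 its median was -0.0063. Matrix glycoproteins and proteoglycans had a median of 0.11 (38 genes, adjusted p = 0.627), with Mfap4 at 2.29 (1.23 without wild-type isolation 2) and Fmod at 2.21 (1.33 without wild-type isolation 2), and without wild-type isolation 1 they passed (median 0.27, adjusted p = 5.3e-04), while without wild-type isolation 2 the median was -0.083.

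The signalling lists and the remaining stress lists did not pass camera. Growth factors and EGF-family ligands had a median of -0.21 (35 genes, camera adjusted p = 0.138). Adjusted over the list alone 1 of them rose, Erbb3, and 3 fell, Pdgfc, Fgf7 and Igfbp4, an IGF-binding protein, at -1.21 (SE 0.146). The fetal growth factor Igf2 differed by 3.99 (SE 0.944, adjusted p = 0.312), at 11.63 and 12.61 in the knockout and 9.43 and 6.83 in the wild type. That list passed with the stricter filter (median -0.30, adjusted p = 0.0439) and with probe sets tested singly (median -0.17, adjusted p = 0.0207), while without knockout isolation 2 its median was -0.00018 (adjusted p = 0.236). Wnt and BMP genes had a median of 0.01 (35 genes, adjusted p = 0.967), with the Wnt modulators Sfrp2 at 3.56 (SE 0.649) and Rspo2 at -2.33 (-1.11 with the mean over its probe sets), and 1 gene, Grem1, fell adjusted over the list alone (-1.36). The TGF-beta list had a median of -0.13 (27 genes, adjusted p = 0.492), with Tgfb2 at -1.37 and Tgfb3 at -0.96 (-0.58 without wild-type isolation 2). Cytokines and chemokines had a median of 0.04 and a downward camera direction (26 genes, adjusted p = 0.618), with Il33 at 2.49 and Ptgs2, which encodes cyclooxygenase-2, at -2.34. Ptgs2 differed by -1.39 without wild-type isolation 2, and Il33 by 1.42 without knockout isolation 1. Interferon-stimulated genes had a median of 0.10 (34 genes, adjusted p = 0.330), with Ifit3 at -1.003 (-0.39 without knockout isolation 2) and Oas1a at 0.95. They passed without knockout isolation 2 (median 0.33, adjusted p = 0.0129) and without wild-type isolation 1 (median 0.21, adjusted p = 0.00845), while the median was -0.054 without knockout isolation 1 and 0.018 without wild-type isolation 2.

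The median was -0.13 for death receptors and apoptosis (30 genes, camera adjusted p = 0.220), with Pmaip1 at -1.59 (-0.70 without knockout isolation 2) and Tnfrsf11b at -0.87. It was 0.05 for the unfolded protein and integrated stress response (30 genes, adjusted p = 0.330), with the serine and glycine synthesis genes Psat1 at 1.22 and Shmt2 at 1.05, and this list passed with probe sets tested singly (median 0.057, adjusted p = 0.0334). Glycolysis and hypoxia genes had a median of -0.21 (22 genes, adjusted p = 0.220), with Egln3 at -0.67 (-0.034 without wild-type isolation 2) and Bnip3 at -0.64, and passed without wild-type isolation 1 (median -0.35, adjusted p = 0.00489) and with probe sets tested singly (median -0.21, adjusted p = 0.0239). Their median was -0.069 without knockout isolation 2 (adjusted p = 0.400), -0.014 without wild-type isolation 2 (adjusted p = 0.919) and -0.32 without knockout isolation 1 (adjusted p = 0.218). Immediate-early genes had a median of 0.01, a mean of -0.05 and a downward camera direction (20 genes, adjusted p = 0.916), with Egr1 at -0.9997 and Btg2 at -0.73 (-0.18 without knockout isolation 2). Egr1 differed by 0.69 without knockout isolation 2.

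**Figure D3:**
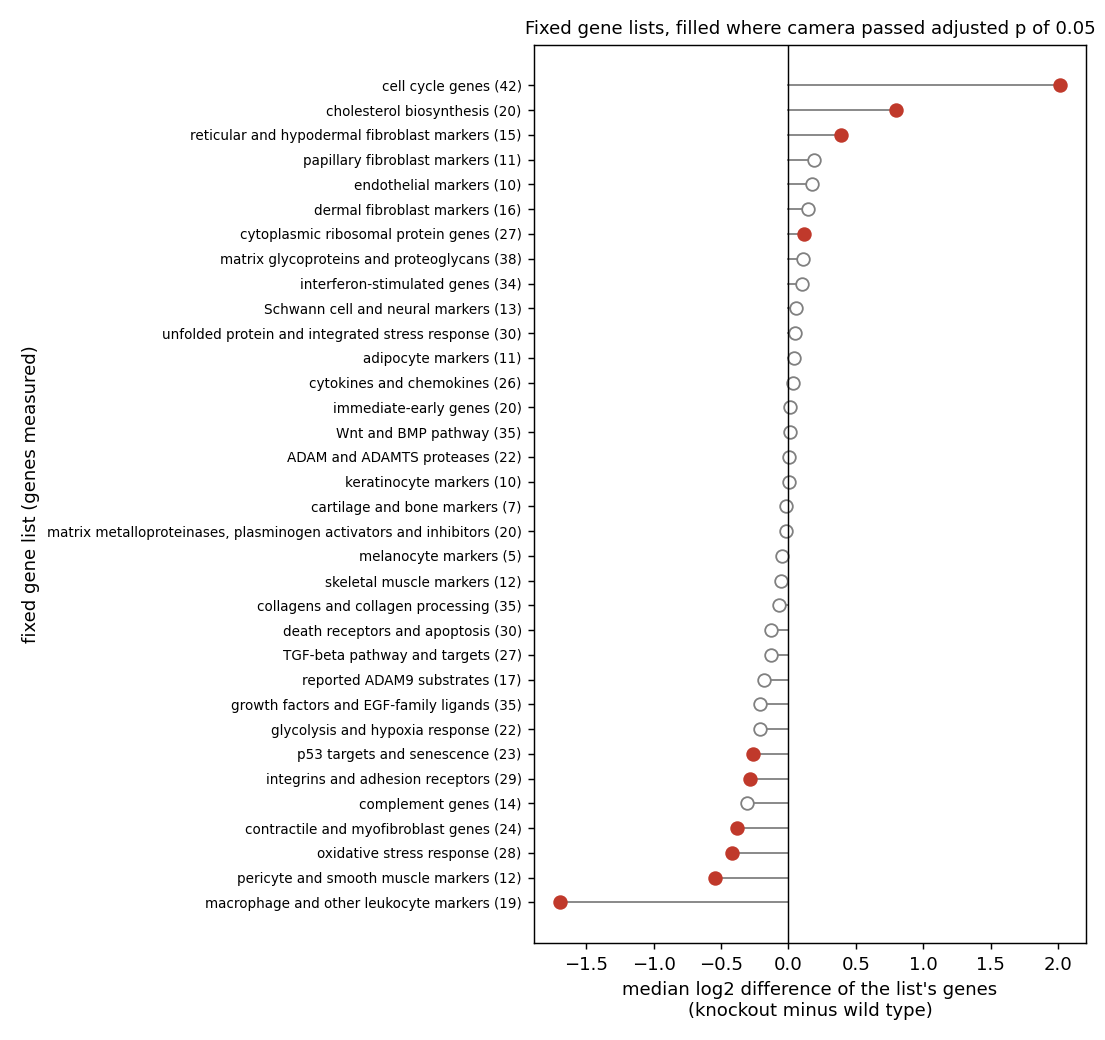
Median log2 difference, knockout minus wild type, of the measured genes of each of the 34 gene lists, with the number of genes in brackets (filled, camera adjusted p under 0.05 with the preset correlation; open, not passed). Cell cycle genes lie farthest to the right at 2.02 and leukocyte markers farthest to the left at -1.70.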

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

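With 2 arrays per genotype, large differences only were within reach of the gene test, and no detection calls were used here to set values against background. Leaving out the X and Y genes was chosen after the data had been seen. Except where stated, the cause of a change was not tested.

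The 9 called genes all remained without a filter, with a floor, with trend and robust eBayes, at 2-fold or more, with each of 3 other normalizations and with array weights. Adam9 lay between -3.31 and -3.08 throughout. Isolation numbers were not treated as pairs, since nothing in the labels says that they mark a shared litter or day. Deviations of same-numbered arrays correlated at 0.116 across genes, which cannot show whether the isolations were paired. With the number as a block, which leaves fewer degrees of freedom, 2 genes passed, 1 higher (Xist) and 1 lower (Eif2s3y). All autosomal calls were lost, and Adam9 (-3.20) had a limma adjusted p of 0.104. Of the lists, 9 passed with the block, and the pericyte list did not. With any array left out, which leaves 1 array in a genotype, assumed to vary like the other, 0 genes passed in all, 0 higher and 0 lower, and Adam9 ran from -3.31 to -3.08 (adjusted p 0.126 to 0.244). The lists that passed then numbered 7 to 13. The 60th percentile filter gave 4 lower genes. Array weights gave 4 higher, the mean over probe sets 1 and leaving out _x_at and _s_at probe sets 0. An adjusted p under 0.1 gave 57 genes, 39 higher and 18 lower. Probe sets tested singly gave 14, 11 of them lower, and 16 lists, the 10 that had passed and those of growth factors, glycolysis, adipocytes, endothelial cells, the unfolded protein response and dermal fibroblasts, with genes of several probe sets counted more than once. Without X and Y genes, 5 genes passed, 1 higher and 4 lower, as 4 called genes were then not tested. Estimated correlation and fry each passed 0 lists.

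Among the 21 settings, those with values for single genes gave 1385 values of 83 other named genes. Of these values, 1337 kept their direction and side of the threshold, but most of the 83 genes had not been called and had no call to lose. The call was lost for 41 values, all of them of called genes, and 5 values gained it. The genes that gained it were Cenpf, in 4 settings, and Nuf2, in 1. Leaving out 1 array moved 38 of the 83 by over 1.5 times or turned their sign, 0 of them called genes. For 12 of them the difference shrank by over 3 times or turned. The mean over probe sets moved 10 by over 1.5 times, and leaving out _x_at and _s_at probe sets 4. With arrays left out in turn, Egr1 ran from -2.69 to 0.69 and Flt1 from -0.035 to 0.53. Of 646 list values, 551 kept direction and side, 39 lost the call, 14 gained it and 42 changed sign, all 42 in lists that had not passed.

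With the 60th percentile filter the medians were -0.13 (Schwann), -0.015 (Wnt and BMP), 0.66 (complement) and -0.11 (immediate-early). Medians that kept their sign but grew under that filter included -0.87 (melanocyte), -0.44 (skeletal muscle), -0.36 (cartilage and bone), 0.32 (adipocyte) and 0.63 (papillary). Without a filter they were -0.030 (immediate-early), -0.013 (keratinocyte) and 0.018 (skeletal muscle). Cyclic loess, median centring and repeated quantile normalization gave 0.0038, 0.0047 and 0.0027 for cartilage and bone. Median centring gave 0.0037 for metalloproteinases, and quantile normalization -0.00067 for Wnt and BMP. Single probe sets gave -0.0033 (ADAM), -0.069 (immediate-early) and 0.060 (melanocyte). The mean over probe sets gave -0.015 for Wnt and BMP and -0.024 for cytokines. With each array left out in turn, medians ran from -0.078 to 0.093 (ADAM), -0.19 to 0.10 (TGF-beta), -0.065 to 0.072 (Wnt and BMP), -0.013 to 0.11 (adipocyte), -0.084 to 0.048 (cartilage and bone), -0.15 to -0.019 (cytokines), -0.030 to 0.37 (dermal fibroblast), -0.14 to 0.064 (immediate-early), -0.054 to 0.33 (interferon), -0.076 to 0.0072 (keratinocyte), -0.083 to 0.27 (matrix glycoproteins), -0.17 to 0.096 (metalloproteinases), -0.099 to 0.011 (melanocyte), -0.034 to 0.41 (papillary), -0.12 to 0.014 (skeletal muscle), -0.042 to 0.18 (unfolded protein), 0.017 to 0.18 (Schwann), -0.15 to -0.0063 (collagens), -0.61 to -0.058 (complement), -0.15 to -0.037 (apoptosis), 0.0023 to 0.26 (endothelial), -0.35 to -0.014 (glycolysis), -0.22 to -0.00018 (growth factors) and -0.16 to -0.12 (ADAM9 substrates).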

Other observations

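The tests of X-linked escape genes, of the changed autosomal genes, of the cell cycle and leukocyte patterns and of windows around Adam9 were chosen after the results were seen. The flank, sex and isolation tests were written beforehand. The imprinting test was also set down beforehand, but it concerns the higher values of Dlk1 and Mest, which are themselves a result.

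Of the 10 tested genes nearest to Adam9 in chromosomal order, 5 had lower and 5 had higher values in the knockout, 3 of them with the opposite sign when an array was left out, and those given here were named after their values were seen. Tm2d2, beside Adam9, was lower by all 8 of its probe sets, by -0.21 to -0.44 on the log2 scale for all but 1, which stood at -1.50. Plekha2 differed by -1.30 (SE 0.202) and Tcim by -1.04 (SE 0.202), while Sfrp1, a Wnt antagonist, differed by 2.12 (SE 0.708; 1.09 without wild-type isolation 2) and Gins4, a replication gene, by 0.79 (SE 0.154). None of these genes passed the limma test (adjusted p = 0.191 to 0.576). X-linked genes reached an unadjusted p under 0.05 in 14.8% of 406 cases, against 11.3% of 12790 autosomal genes (two-sided Fisher's exact p = 0.039). That test counts genes as independent units and does not measure the spread between isolations. A further 4 probe sets passed when probe sets were tested singly, all lower in the knockout, by -5.12 to -7.61. These named either no gene or several genes in the platform annotation.

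For the called genes, the first pattern, limma with the arrays split by isolation number instead of genotype called 0 genes (394 at an unadjusted p under 0.05; 0 and 122 for the crossed split, 9 and 1516 for the genotypes), but such a split leaves the genotype difference in the residual spread and decides nothing about a batch shared by same-numbered isolations. The measured Y-linked genes had a median difference of -5.02 and the X-linked genes Kdm6a, Eif2s3x, Kdm5c and Ddx3x, which escape inactivation, one of 0.54, consistent with female knockout and male wild-type pups as the source of the sex-linked calls. For the autosomal calls, 0 arrays had the sex-linked expression of the other genotype, so sex and genotype cannot be told apart. DNA of another strain carried around the targeted locus may add differences. Of 196 tested neighbours of Adam9, 36 (18.4%) had an unadjusted limma p under 0.05, against 11.3% of the other genes. As high a share was reached by 3.90% of 9085 autosomal windows of that size, which overlap each other and are not independent. For called genes the odds ratio was 0 with an upper 95% limit of 101, which leaves this explanation open there. Ifi202b is known to differ between inbred strains, and strain was not tested.

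The second pattern is the higher level of cell cycle genes in the knockout. Dilution by leukocyte RNA in wild-type isolation 1 would not lower them in wild-type isolation 2, yet the lower knockout array lay 1.83 log2 units above that array in the list's median. The list's median lay 2.01 above that of the 50 genes nearest to each member in mean level, and 10000 random lists of such genes had medians of -0.188 to 0.242, which argues against a scaling of arrays that shifts genes of a like level together. Faster growth without ADAM9 is a hypothesis that may account for it, but so may pup sex or the growth state of the plates, and with 0 arrays of the other sex in either genotype they cannot be told apart.

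The third pattern is the leukocyte genes. Their median in wild-type isolation 1 lay 3.78 log2 units above the highest other array, which fits leukocytes in that culture alone, a hypothesis under which the list's difference may say little of the genotype. The abundant macrophage gene Lyz2 stood at 12.56 there and at 6.78 to 7.59 in the other arrays, and Tyrobp at 9.49 and 3.98 to 4.65. The T cell gene Cd3e stood at 5.31 to 5.63 in all arrays. These 3 genes were chosen after their values were seen. No biological explanation could be tested with 1 such array.

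Dlk1 and Mest (2.29, SE 0.971), both imprinted, had higher values in the knockout, and Mest was named after its value was seen. Mest was 9.08 and 6.25 in the wild-type arrays, and without wild-type isolation 2 it differed by 0.88. Whether imprinted genes shifted together was tested on 10 others, of which 9 were measured. Their median difference was 0.019, with members that went both ways, from -0.27 to 3.99. The largest difference was that of Igf2, which had the direction of Dlk1 and Mest. A median over members so unlike decides nothing for these genes.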
